A study of Mus musculus with 15 samples.

How the data were processed

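Total RNA was extracted from the ipsilateral basal ganglia with TRIzol and labelled with Cy3, per the labels' protocols, and each of the 15 samples had its own array. The deposited scanner files hold spot intensity values from Agilent Feature Extraction 11.0.1.1, per the file headers. The intensity used was the processed signal, which the software had corrected for background within each array and had not scaled between arrays. Its flags for spots well above background, saturated or outlying were used as given. A deposited table holds log2 values for 34099 probes, and how the authors made them is not given in the sources used here. Each of its columns followed its own array's quantile-normalized values most closely, with r of 0.959 to 0.986 across probes after each probe's mean was removed, and its column medians ran from 6.50 to 6.54. Without any centring, its values differed from those quantile-normalized log2 values by 0.129 to 0.140 on average per array. Its scale and level are thus close to theirs. It served as an alternative.

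Each array has 62976 spots, of which 1439 are control spots. Outlying spots were left out (25 to 93 per array), replicate spots of a probe were averaged on the log2 scale, and no spot was saturated. Each array's 75th percentile over the other probes was subtracted from the log2 intensity. Probes named as spike-ins, custom or negative probes (132) and those with a left-out value on any array (169) were not tested. A probe was tested when it was well above background on at least 5 of the 15 arrays, which left 51669. A bound ("at least") sets the mean of the bright group against the higher of the dim probe's own signal and the lowest signal well above background on each array of the dim group.

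Gene names came from accessions in the scanner files, matched without versions to the RefSeq table of mouse genes (GRCm38.p6). Of 50 probes with an accession, 46 matched a symbol and 45 of these were tested, each symbol having 1 probe. The files do not pair the other probes with genes, so at most 2 probe identifiers that rose and 2 that fell are printed, fewer than the 5 and 5 first planned for long noncoding RNAs. The meaning of the probe name classes is not stated in the files.

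Groups came from the sample titles. The comparisons were ICH against sham, BYHWD against ICH and BYHWD against sham, fitted together with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 15 arrays, 2-sided, with Benjamini-Hochberg adjusted p under 0.05 over the tested probes. The design, the gene lists, the rule for named genes and the alternatives, except those stated as chosen later, were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among named genes past the threshold with no overlap between the groups' arrays. Where fewer than 5 passed in a direction, the smallest p values filled up to 5, stated as not past the test. It added 22 fixed genes, of which Apoe and Mbp have a named probe, and members of the lists, of which 1 is not reported here. The set tests planned for the lists (camera, at least 5 tested members) could not be run, since no list had more than 1 tested member.

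The score along the injury change was the mean log2 level of probes higher in ICH minus that of probes lower in ICH, centred on the sham mean. The probes came from 5 fits that each left out 1 ICH array (300 to 4350 probes), and BYHWD arrays took the mean over the 5. Its test was an exact permutation test of the 252 groupings, whose smallest possible p is 0.00794, and the interval came from inverting it. Slides were read from the scan identifiers of the files. The slide was used as a fixed block for ICH against sham and as a random block (duplicateCorrelation) otherwise. The day of scanning was the same for all arrays and could not serve as a block.

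The limma step was tested on simulated arrays built from the means and spreads of the 51669 probes, for ICH against sham with 200 changed probes. It recovered 12% of those changed 1.5-fold, 78.5% of those changed 2-fold and 98% of those changed 4-fold, each with the right sign, and made 1, 6 and 5 false calls. The simulated noise was independent between arrays and between probes and held no slide effect. These counts therefore do not measure false calls in the real arrays. Replicate numbers came from the titles. Alternatives covered normalization, background correction, the filter, the variance model, blocks, thresholds and each array left out.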

Results

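RNA from the ipsilateral striatum of male mice was measured on 15 one-colour Agilent arrays, 5 per group. The groups were sham mice given water, mice with intracerebral hemorrhage (ICH, bleeding into the brain tissue) given water, and mice with ICH given Buyang Huanwu decoction (BYHWD), a herbal formula of traditional Chinese medicine. The decoction was given by gavage at 6.19 g/kg each day, and tissue was taken at day 14. The stated purpose was to find expression signatures of the decoction in this injury. The labels number 5 samples per group and do not state that each came from a separate mouse, so p-values measure the spread between these samples. Between 81.4% and 86.2% of the spots on each array were well above background, and the 75th percentile of the signal ranged from 257 to 529 units. The number of arrays limits the precision of every value below.

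Few probes could be tied to a gene. Of the 51669 tested probes, 45 carried an accession that matched a gene symbol, and the others are known here only by the manufacturer's identifier. The genes named below are therefore those 45 genes, not a survey of the striatum. Of the 37 gene lists fixed for this tissue and injury, 6 had 1 tested member each and the others had none, so no list could be tested. Among these members were Apoe from the disease-associated microglia list, Mzb1 from B and plasma cells, Mbp from myelin, Gsdmd from cell death and Gpi1 from glycolysis.

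The arrays had been scanned on 3 slides. Slide 1 held the 5 sham arrays with ICH 2 and ICH 3, slide 2 held ICH 1, ICH 4 and ICH 5, and slide 3 held the 5 BYHWD arrays. The first principal component of the tested probes (35.3% of the variance) placed the 3 ICH arrays of slide 2 between 84.3 and 88.9, while ICH 2 and ICH 3 lay at -37.1 and -31.0, within the sham range of -70.2 to -34.0 or close to it. Between the ICH arrays of slide 2 and those of slide 1, 11320 probes passed the limma test. ICH and sham can thus be compared within slide 1, whereas BYHWD shares no slide with another group, and slide and group cannot be told apart in either comparison that includes it. As a sign of RNA integrity, the Gapdh control probe at the 3' end exceeded that at the 5' end by 0.23 ± 0.15 log2 units in sham, 0.61 ± 0.19 in ICH and 0.48 ± 0.10 in BYHWD (SD, n = 5 each). The 2-sided exact permutation p was 0.0159 for ICH against sham and 0.0238 for BYHWD against sham, each with an adjusted p of 0.05 over 21 tests, which is not under the threshold. The same difference for Pgk1 was 7.51 ± 0.14 in sham, 7.67 ± 0.17 in ICH and 7.88 ± 0.06 in BYHWD (SD, n = 5 each), and passed for BYHWD against sham (difference 0.37, higher on all 5 BYHWD arrays, 2-sided exact permutation p = 0.00794, adjusted p = 0.0417). On every array it was large (7.36 to 7.93), so it sets a bright probe against a far dimmer one and is a weak sign of RNA integrity.

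**Figure D1:**
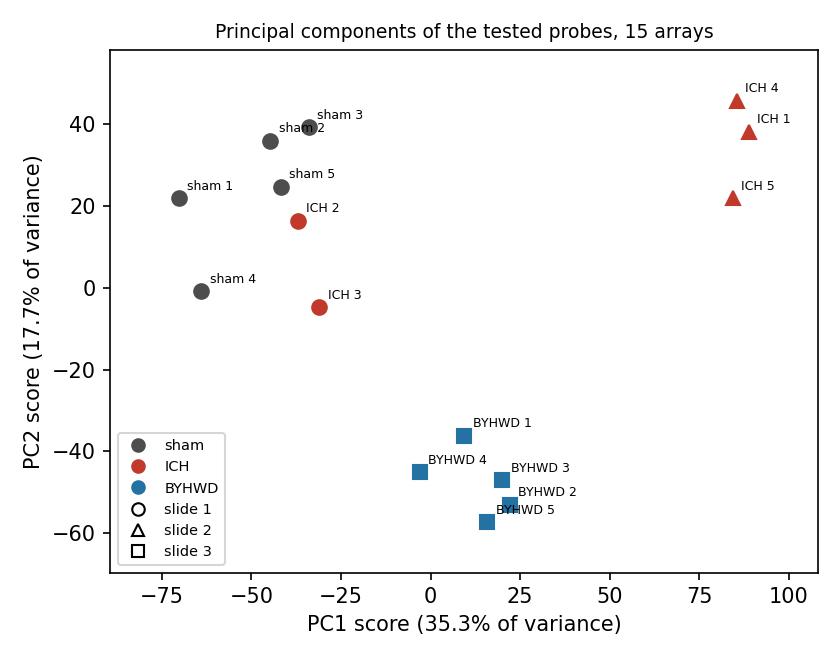
Scores of the 15 arrays on principal components 1 and 2 of the 51669 tested probes, each axis labelled with its percent of variance, coloured by group and with the marker shape giving the slide. ICH 1, ICH 4 and ICH 5 (slide 2) sit between 84.3 and 88.9 on component 1, and the other 2 ICH arrays lie beside the sham arrays.

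**Figure D2:**
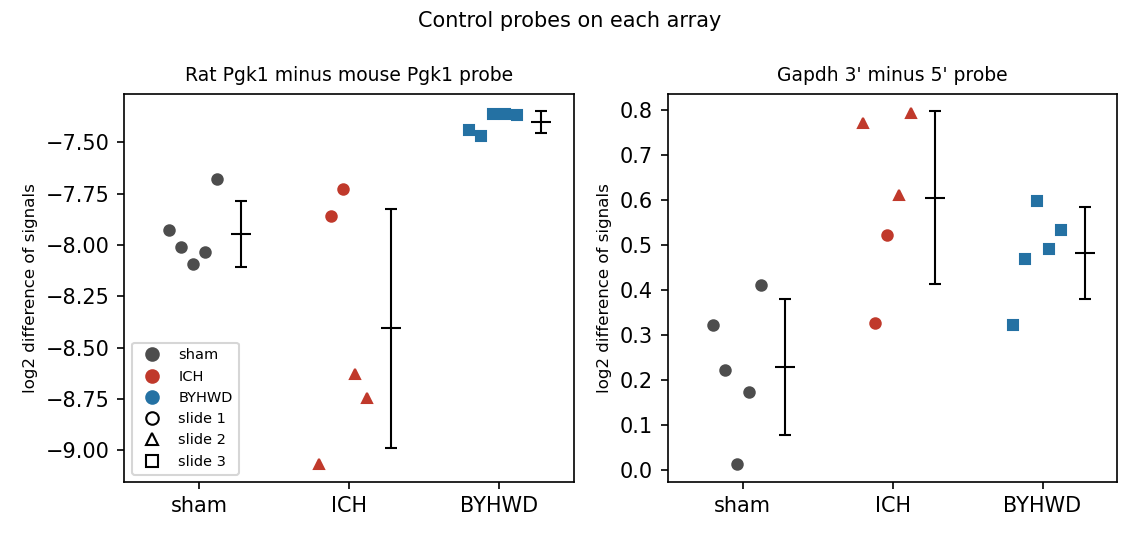
Log2 difference between control probes on each array, by group, with the marker shape giving the slide: rat Pgk1 minus mouse Pgk1, and Gapdh at the 3' end minus Gapdh at the 5' end. The Pgk1 difference lies between -9.07 and -8.63 on slide 2, between -8.09 and -7.68 on slide 1 and between -7.47 and -7.36 on slide 3.

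The first comparison asked what differed in the striatum 14 days after hemorrhage. H2-Q7, a class I histocompatibility gene, was 3.52-fold higher in ICH than in sham, from a log2 level of 1.90 ± 0.35 to 3.71 ± 0.45 (SD, n = 5 each; log2 difference 1.82 ± 0.27 SE, limma adjusted p = 0.00424). Gsdmd, which encodes the pore-forming protein of pyroptotic cell death, was 1.96-fold higher (log2 difference 0.97 ± 0.17 SE, limma adjusted p = 0.00861). Apoe, the lipid carrier of the brain made by astrocytes and by activated microglia, was 1.92-fold higher (log2 difference 0.94 ± 0.17 SE, limma adjusted p = 0.0084). For these 3 genes all 5 ICH arrays lay above all 5 sham arrays. On slide 1 the differences of the 2 ICH arrays from sham were 1.85 for H2-Q7 (limma adjusted p = 0.0447), 1.20 for Gsdmd (adjusted p = 0.0344) and 1.13 for Apoe (adjusted p = 0.0403) on the log2 scale. These p-values take the spread from all 15 arrays. Without the ICH arrays of slide 2 in the fit, none of the 3 genes passed. Over the 28 alternatives the largest adjusted p for each of the 3 was 0.0576, reached without the ICH arrays of slide 2, and the lowest were 0.000813, 0.00246 and 0.00111. H2-Q7 belongs to a family of nearly identical genes, so its probe may read relatives too.

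Mzb1, a chaperone of B and plasma cells, was 1.61-fold higher in ICH (log2 difference 0.69 ± 0.16 SE, limma adjusted p = 0.0269), and Il2, the T-cell growth cytokine, was 2.23-fold higher (log2 difference 1.16 ± 0.31 SE, limma adjusted p = 0.0434), from a dim probe with overlapping groups. For Mzb1 all 5 ICH arrays lay above all 5 sham arrays. Neither gene passed within slide 1. Against sham, the log2 difference of Il2 was 1.82 for the 3 ICH arrays of slide 2 and 0.17 for the 2 of slide 1 (limma adjusted p = 0.988), and that of Mzb1 was 0.96 and 0.29 (adjusted p = 0.844 within slide 1). Their adjusted p ranged from 7.26e-07 to 0.988 for Il2 and from 5.43e-05 to 0.844 for Mzb1 over the alternatives, in which 21 of 27 and 13 of 28 were not past the test. Il2 was no longer past the test without any 1 of 13 of the 15 arrays (largest adjusted p 0.133). Mzb1 was no longer past it without sham 1, sham 2, sham 4, sham 5, ICH 1, ICH 4 or ICH 5 (largest 0.0878). The log2 difference of Mzb1 was lowest at 0.23 after normexp with quantiles, whose offset of 50 units shrinks the differences of dim probes.

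None of the 45 named genes was lower in ICH past the test. The 5 smallest p values in that direction belonged to the olfactory receptor gene Olfr166 (log2 difference -0.71, adjusted p = 0.0758), the homeobox gene Lhx1 (-0.45, adjusted p = 0.0833), the peroxisome gene Pex11a (-0.40), the oxidase gene Duox1 (-0.28) and Spats1 (-0.20). Within slide 1 and for the ICH arrays of slide 2 against sham, Olfr166 stood at -0.02 and -1.16, Lhx1 at -0.08 and -0.70, Pex11a at 0.11 and -0.74, Duox1 at -0.09 and -0.41 and Spats1 at -0.01 and -0.33. Mbp, the basic protein of myelin, differed by 0.19 ± 0.11 SE (limma adjusted p = 0.279), and Gpi1, a glycolytic enzyme, by 0.21 ± 0.11 SE (limma adjusted p = 0.221). Adjusted over the 45 named genes alone, 7 passed, among them Hyal3 and Olfr166 in addition to the 5 above.

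**Figure D3:**
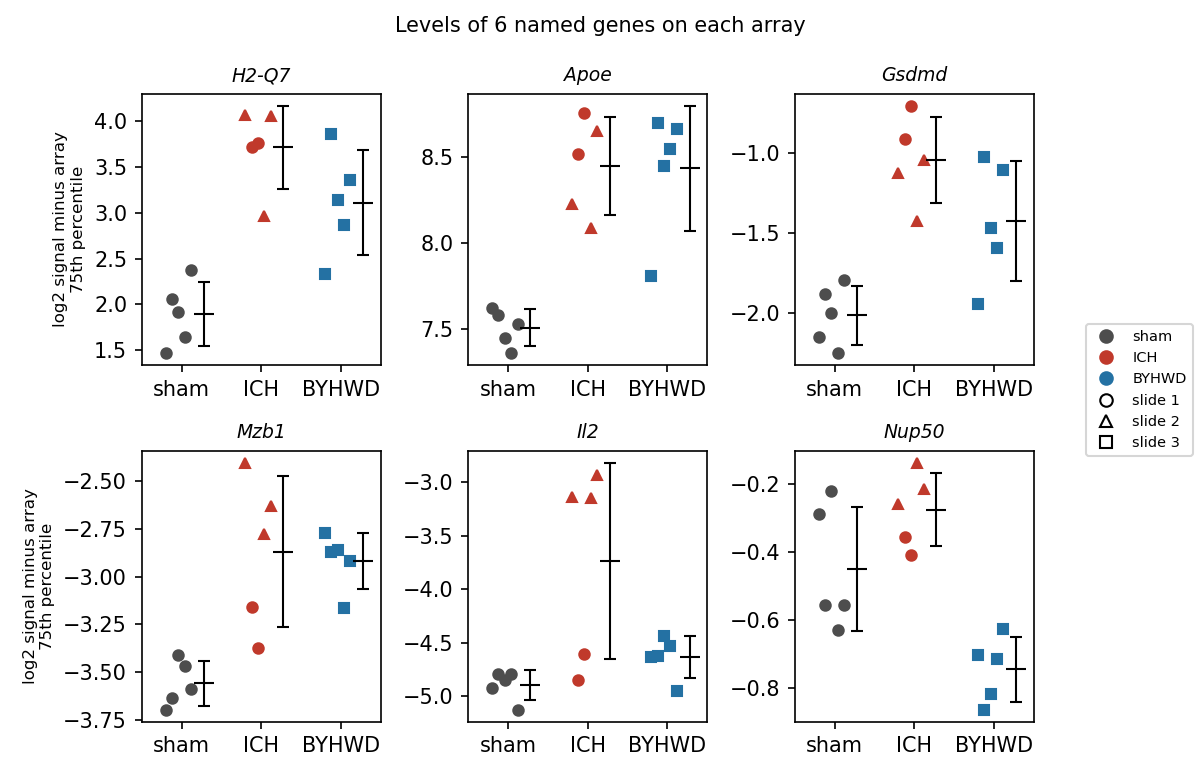
Log2 signal minus the array's 75th percentile for H2-Q7, Apoe, Gsdmd, Mzb1, Il2 and Nup50, 1 point per array, with the marker shape giving the slide and the bar giving the group mean ± SD (n = 5). H2-Q7, Apoe and Gsdmd of the ICH arrays lie above sham on both slides, while Il2 is high on the 3 ICH arrays of slide 2 only, with log2 differences from sham of 1.82 there and 0.17 on slide 1.

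Over all tested probes, 2066 were higher and 489 lower in ICH than in sham (2555 of 51669 at an adjusted p under 0.05, limma), and 764 of them differed at least 2-fold. With the slide as a fixed block, where the difference rests on slide 1 and the spread on all arrays, 178 probes were higher and 3 lower. After quantile normalization 65 passed between these ICH arrays and sham, and without the ICH arrays of slide 2 in the fit 27 did. Of the 181, 167 also passed in the same direction between the ICH arrays of slide 2 and sham. Both sets of arrays were set against the same sham arrays, which raises this overlap by chance. Leaving out single arrays moved the pooled count from 438 (without ICH 5) to 10389 (without ICH 2), and each sham or ICH array moved it by over 1.5 times. The split between higher and lower moved too, to 5994 and 4395 without ICH 2, to 5314 and 4514 without ICH 3 and to 429 and 9 without ICH 5. Among the probes whose names carry LNC, ASMM10LNC1A100015517V4 was at least 5.51-fold higher in ICH (limma adjusted p = 0.00112, well above background on 2 of 5 sham and 5 of 5 ICH arrays). ASMM10LNC1A100009479V4 was not well above background on any sham array and was at least 2.60-fold higher in ICH (limma adjusted p = 0.00584). Among LNC probes past the test with no overlap between the groups, the largest falls were of ASMM10LNC1A104296140V4 (-2.35 ± 0.60 SE) and ASMM10LNC1A106792409V4 (-1.94 ± 0.49 SE). These stood at -0.36 and -0.37 within slide 1 and at -3.67 and -2.99 for the ICH arrays of slide 2 against sham.

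The treatment comparison asked what differed in ICH mice given the decoction. Nup50, a nuclear pore protein gene, was lower in BYHWD than in ICH (log2 difference -0.47 ± 0.10 SE, 0.722-fold, limma adjusted p = 0.0224), with all 5 BYHWD arrays below all 5 ICH arrays. Trp53rka, a kinase gene with a nearly identical copy, was 0.785-fold as high at the edge of the threshold (log2 difference -0.35 ± 0.10 SE, limma adjusted p = 0.0499), with overlapping groups. It was no longer past the test in 19 of 27 alternatives, whose adjusted p ranged from 0.0164 to 0.768. No named gene was higher past the test, and the smallest p values in that direction belonged to Duox1 (log2 difference 0.48, adjusted p = 0.0569), Olfr166 (0.73, adjusted p = 0.0659), Lhx1 (0.47, adjusted p = 0.0756), Spats1 (0.19) and Actb (1.22). Also not past the test, on the lower side, were Alkbh4, a demethylase gene (log2 difference -0.28, adjusted p = 0.0816), Il2 (-0.90, adjusted p = 0.085) and Atg3, an autophagy gene (-0.35, adjusted p = 0.0943). Several of these values depended on the slide of the ICH arrays. Against the ICH arrays of slide 1 and of slide 2, the log2 difference was 0.09 and -1.56 for Il2, 3.46 and -0.28 for Actb, 0.05 and 1.19 for Olfr166, 0.10 and 0.72 for Lhx1 and 0.00 and 0.32 for Spats1. It was -0.36 and -0.54 for Nup50, which did not pass against slide 1 (limma adjusted p = 0.0993). Adjusted over the named genes alone, 1 passed.

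The genes that were higher in ICH on both slides did not differ between BYHWD and ICH past the test. The log2 difference was -0.01 ± 0.17 SE for Apoe (limma adjusted p = 0.965), -0.60 ± 0.27 SE for H2-Q7 (limma adjusted p = 0.158) and -0.38 ± 0.17 SE for Gsdmd (limma adjusted p = 0.169).

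Over all tested probes, 1886 were higher and 1288 lower in BYHWD than in ICH, and 286 of the 3174 differed at least 2-fold. The split and the calls depended on the slide of the ICH arrays. Against the 2 ICH arrays of slide 1, 3013 probes were higher and 682 lower, and against the 3 of slide 2, 7879 and 6405. Of the 3174, 918 passed in the same direction against slide 1 and 2982 against slide 2. With the slide as a random block 1 probe passed limma's test, at a between-array correlation of 0.36 within slides, and 3217 had an unadjusted p under 0.05. Since BYHWD fills a slide of its own, this fit has little power for it. The log2 difference of Nup50 was then -0.46 ± 0.17 SE, nearly unchanged, and with the wider error its adjusted p was 0.768, the largest of its 27 alternatives, the lowest being 0.00429. Among the other alternatives, Nup50 was not past the test without BYHWD 2 or without BYHWD 3 (largest adjusted p 0.0563) and without the ICH arrays of slide 2. Leaving out single arrays gave 953 (without BYHWD 3) to 6323 probes (without ICH 3).

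BYHWD was also set against sham, to show how far the treated mice lay from uninjured ones. Apoe was 1.90-fold higher in BYHWD (log2 difference 0.93 ± 0.17 SE, limma adjusted p = 0.00275), H2-Q7 2.32-fold (1.21 ± 0.27 SE, adjusted p = 0.0077), Hyal3, a hyaluronidase gene, 1.65-fold (0.72 ± 0.16 SE, adjusted p = 0.00824), Mzb1 1.56-fold (0.64 ± 0.16 SE, adjusted p = 0.0132) and Gsdmd by 0.59 ± 0.17 SE on the log2 scale (adjusted p = 0.0306). Hyal3 differed by slide within ICH, at 0.18 against sham on slide 1 (limma adjusted p = 0.988) and 0.75 on slide 2. BYHWD differed in Hyal3 from the ICH arrays of slide 1 by 0.55 and from those of slide 2 by -0.02. No named gene was lower past the test, and the smallest p values belonged to Nup50 (log2 difference -0.30, adjusted p = 0.0609), Ppara, a nuclear receptor of fatty acid use (-0.22), Uhrf1bp1l (-0.22), Alkbh4 (-0.19) and Prdx2, a peroxiredoxin (-0.20). Over all probes 6541 were higher and 2431 lower, and quantile normalization changed the split to 4907 and 3468. With the slide as a random block 3 probes passed limma's test, with 4288 at an unadjusted p under 0.05. In that fit, which has little power here too, the log2 differences were 1.02 ± 0.29 SE for Apoe, 1.23 ± 0.49 SE for H2-Q7, 0.56 ± 0.26 SE for Hyal3, 0.45 ± 0.24 SE for Mzb1 and 0.70 ± 0.30 SE for Gsdmd. With these wider errors none of the 5 genes passed, and their adjusted p lay between 0.384 for Apoe and 0.633 for Mzb1, the largest of the 27 alternatives for each gene, the lowest being 0.000567 for Mzb1 and 0.00565 for Gsdmd. After normexp with quantiles the log2 difference fell to 0.21 for Mzb1 and 0.32 for Hyal3, both still past the test. Normexp added an offset of 50 units, which by itself shrinks the differences of dim probes such as these 2 (mean signal 42.8 and 67.9 units). Gsdmd was also no longer past the test with quantile normalization, with or without normexp, and without sham 1, sham 3, sham 4, BYHWD 2, BYHWD 3 or BYHWD 5 (largest adjusted p 0.0840).

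A score along the change from sham to ICH asked whether the BYHWD arrays lay nearer to sham than the ICH arrays did. Each ICH array was scored on 1 set of probes chosen without it, and each BYHWD array by its mean over the 5 sets. The 2 kinds of score are thus not fully interchangeable, so the p-value and interval are approximate. The score was 1.45 ± 0.38 in BYHWD and 1.83 ± 1.01 in ICH (SD, n = 5 each), a difference of -0.38 (95% interval -1.47 to 0.86, 2-sided exact permutation test p = 0.452). Leaving out single arrays moved it from -1.08 (without ICH 3) to -0.02 (without ICH 5), and on probes above background on all 15 arrays it was 0.040 (exact p = 0.881). The ICH arrays of slide 1 scored 0.41 and 1.21 and those of slide 2 scored 2.05 to 2.85, while the BYHWD arrays ranged from 0.90 to 1.89, overlapping the range of slide 1. The ICH arrays were each scored on a different set of probes. For an ICH array of slide 1, that set came from a fit whose ICH arrays were mostly of slide 2. The score thus differed by slide within ICH, but part of that gap may come from the choice of probes. BYHWD fills a slide of its own, so the score cannot tell treatment from slide.

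Among the probes that passed in both ICH against sham and BYHWD against ICH, 146 changed in opposite directions and 37 in the same direction. With the slide as a block, where 1 probe is left in the second comparison, the overlap was 0. Leaving out single arrays gave 6 (without ICH 5) to 2036 (without ICH 3), each of the 15 arrays moving it by over 1.5 times. Of the 146, 94 were higher in ICH and then lower in BYHWD, and 52 the reverse. None of the 146 was a named gene. Independent lists would share 51.5 and 17.8 probes, which leaves out the shared ICH arrays. In 100 simulated BYHWD groups unchanged from ICH the overlap was at most 2, but few probes can pass there, so this value gives no measure of what the shared arrays add. Neither takes the slides into account. The covariance of the 2 sets of log2 differences was -0.0610 against -0.0202 in the simulations (across probes, which are not independent). With the ICH arrays divided between the comparisons in 20 ways, the overlap ranged from 0 to 73 probes with a median of 0.5, and the covariance from -0.0726 to 0.0954, so how much of the overlap comes from the shared ICH arrays stays open.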

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

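The fits with the slide as a block were fixed in advance, while the use of the random block as a test of the slide for BYHWD against ICH, the test of the slide within slide 1, the fit without the ICH arrays of slide 2 and the test of the control probes were chosen only after the results they bear on had been seen.

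Within groups of 5, 7 of 86 checked sets of values had an array far from the others, where chance gives about 1 in 20. Mbp was 7.82 on sham 4 against 8.14 to 8.22 on the other sham arrays (gap over range 0.785). Apoe was 7.81 on BYHWD 1 against 8.45 to 8.70 (0.717). Trp53rka was -1.46 on ICH 3 against -1.35 to -1.31 (0.722) and -1.38 on BYHWD 4 against -1.85 to -1.72 (0.714). On BYHWD 3, Duox1 was -0.65 against -0.46 to -0.38 (0.721) and Lhx1 was -0.15 against 0.08 to 0.13 (0.800). Ppara was -2.10 on BYHWD 2 against -1.92 to -1.85 (0.721). Outside the tested probes, the control probe named for rat Pgk1, relative to that named for mouse Pgk1, was higher on all 5 BYHWD arrays than on any sham array, by 0.547 log2 units on average (exact permutation p = 0.00794, the smallest 5 against 5 can give, adjusted p = 0.0417 over 21 tests). It was also higher on all 5 BYHWD arrays than on any ICH array, by 1.01 on average (exact permutation p = 0.00794, adjusted p = 0.0417). This control thus separated the 2 groups of the treatment comparison. The 75th percentile of the signal was lower in BYHWD than in sham (332 against 474 units on average, exact permutation p = 0.00794, adjusted p = 0.0417).

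The 2555 probes that passed between ICH and sham were exceeded or matched by 3 other splits among the 100 drawn, the real one making 4. The highest reached 6595 probes, and all 3 kept the 3 arrays of slide 2 on the same side, as 15 of the drawn splits did. Drawn splits that parted these arrays gave at most 52 probes. The count thus follows slide 2. Among groupings that keep slide 2 together the real one does not stand out, so chance stays open there. Of the probes that passed between the ICH arrays of slide 2 and 3 sham arrays, 44.2% to 75.04% had the same sign in the ICH arrays of slide 1 against the other 2 sham arrays. That range over 10 divisions of the sham arrays spans the 50% a slide effect alone would give, so the slide and the hemorrhage cannot be told apart for these probes, although the lowest share met the bound set in advance for a slide effect. Within slide 1, where a slide effect is excluded, 227 probes passed in a fit of its 7 arrays, the largest count among its 21 splits (1 as large, the highest other 153), against 181 in the fit of all arrays with the slide as a block (65 after quantile normalization) and 27 in that without the ICH arrays of slide 2, and the hemorrhage and the position on the slide stay open for those.

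For BYHWD against ICH, 1 of 100 splits gave as many probes, the real one with 3174, the highest other having 856. No other drawn split came near, but each of them parted the arrays of slide 3, so the splits do not tell group from slide. The treatment and slide 3 cannot be told apart, because every BYHWD array lies on slide 3. With the slide as a random block 1 probe passed, but this design leaves that fit little power whatever the cause, so the count decides nothing (Nup50 stood at -0.46 ± 0.17 SE there against -0.47 ± 0.10 SE without the block). For BYHWD against sham, 1 of 100 splits gave as many probes (real 8972, highest other 87), with the same confounding by slide.

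The ICH arrays of slide 2 stood apart from those of slide 1. A difference in hybridization or washing is a candidate explanation, since the rat-to-mouse Pgk1 ratio was -9.07 to -8.63 on slide 2 and -8.09 to -7.68 on slide 1, a gap of 0.538 log2 units. An array-wide difference in brightness as the whole cause is argued against, as 81.1% of the probes that passed between the 2 sets of ICH arrays also passed after quantile normalization. That step cannot remove effects of weak signal that differ between probes, so those stay open. The Gapdh 3' to 5' difference also lay apart, at 0.61 to 0.79 on slide 2 against 0.33 to 0.52 on the ICH arrays of slide 1, and neither RNA integrity nor the extent of injury was tested as a cause, so both stay open.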

How the results depend on the processing

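Normexp background correction, the random slide block for ICH against sham, leaving out the ICH arrays of 1 slide and the score on slide 1 probes were chosen after seeing the data. Of the 22 named genes over all comparisons, leaving out single arrays left 925 results on the same side of the threshold, moved 24 past it and took 41 below it, and the other alternatives gave 723, 54 and 33, with 1 reversal. That was Spats1 in BYHWD against sham, at 0.18 under normexp with the 75th percentile (limma adjusted p = 0.0463). Counts are given below in the order ICH against sham, BYHWD against ICH, BYHWD against sham and the opposite-direction overlap, only where they moved by over 1.5 times. The cause was not tested unless stated.

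Quantile normalization moved the overlap to 228. Normexp with the 75th percentile gave 19605, 1352, 20486 and 243, with the median of all probes shifted by 0.18 in ICH and 0.16 in BYHWD against sham. Normexp with quantiles gave 5104 for BYHWD against ICH and an overlap of 243. The deposited values gave 163 for ICH against sham, 4955 for BYHWD against sham and an overlap of 19. They hold fewer probes, and on 31704 shared probes ICH against sham gave 994 with the main values, 355 with quantiles and 666 with the deposited values. Without the filter on dim probes the overlap was 95. Fitting only the groups compared gave 616, 1740 and an overlap of 13, with fewer arrays to estimate the spread. Trend and robust estimation gave an overlap of about 2.4e+02. Array weights gave 14925, 11427, 15596 and 5172.

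The slide as a fixed block gave 181 for ICH against sham. As a random block it gave 359, 1 and 3 for the comparisons, and the overlap was 0 with either kind of block (limma, with 3217 probes at an unadjusted p under 0.05 for BYHWD against ICH). Without the ICH arrays of slide 2, ICH against sham gave 27 and the overlap 5. Without those of slide 1, the counts were 18046, 13389 and an overlap of 8556. A 2-fold difference left 764, 286 and 1379, fewer by construction, and an unadjusted p with a 1.5-fold difference (2 changes) gave 5858 for ICH against sham.

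Same-numbered arrays did not deviate together (correlations -0.341 to 0.0905), and an array correlated best with its own number in 0, 0 and 1 of 5 cases, so the numbers were not taken to pair the samples. With the replicate number as a block the counts were 1159 and 601 with an overlap of 18. Il2 and Mzb1 in ICH against sham and Nup50 and Trp53rka in BYHWD against ICH were then not past the threshold (no other named gene was lost). The paired sign-flip test of the injury score gave an exact p of 0.5625, the smallest possible being 0.0625.

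Leaving out single arrays gave 438 (ICH 5) to 10389 (ICH 2) for ICH against sham, 953 (BYHWD 3) to 6323 (ICH 3) for BYHWD against ICH, 5518 (BYHWD 2) to 9537 (ICH 2) for BYHWD against sham and 6 (ICH 5) to 2036 (ICH 3) for the overlap. ICH against sham moved by over 1.5 times without any sham or ICH array. BYHWD against ICH did so without sham 5, ICH 1, ICH 3, ICH 4, ICH 5 or any BYHWD array, and BYHWD against sham without BYHWD 2. The overlap did so without any 1 of the 15 arrays. The injury score difference ranged from -1.08 (ICH 3) to -0.02 (ICH 5) and was reversed at 0.040 (exact p = 0.881) on probes above background on all 15 arrays. On slide 1 probes the 3 ICH arrays of slide 2 scored 1.55 ± 0.43 and the BYHWD arrays 1.47 ± 0.88 (SD, exact permutation p = 0.911).

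The planned normexp on gMeanSignal was not run, since the scanner files used here give a median spot signal, nor were the gene list tests, for want of members, and the scan date block, as all arrays shared 1 day. Between 81.4% and 86.2% of the spots per array were well above background, which limits what dim probes can show.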

Other observations

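Of the 1030 tested probes grouped here as lincRNA by the start of their names, 289 were higher and 22 lower in BYHWD than in sham (limma). Thus 30.2% passed, against 17.4% of all tested probes. Against ICH, 90 were higher and 2 lower in BYHWD (8.93% against 6.14%). The class takes names that start with humanlinc or mouselinc, among others. Another dim class, with names carrying UP (median signal 18.0 units), stood at 22.5% against sham and 4.94% against ICH. Whether the lincRNA class stood apart from the other probes was not tested. After quantile normalization these counts were 208 and 28, and 100 and 7. With the slide as a random block, a fit with little power for BYHWD, none passed, and their median log2 difference from sham was 0.27. These probes are dim, with a median signal of 13.5 units over the 1806 on the array, and which genes they read is not given in the sources used here.

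The Actb probe lay between -3.68 and 0.53 on the 7 arrays of slide 1, between 1.34 and 2.08 on the 3 of slide 2 and between 1.08 and 1.85 on the 5 of slide 3. Within ICH the difference between slides 2 and 1 was 3.74 log2 units (limma adjusted p = 0.00346), while BYHWD against ICH gave 1.22 (limma adjusted p = 0.351). Actb has many processed pseudogenes, whose transcripts its probe could not be shown to exclude. The mean signal of this probe was 433 units, against 30876 for Gpi1 and 111571 for Mbp. Whether it follows the level of Actb mRNA was not tested. The spike-in probe for ERCC-00062 was at 4.12 to 4.96 on slide 2, at 5.46 to 6.40 on slide 3 and at 6.20 to 7.38 on slide 1.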
